A study of Mus musculus with 18 samples.

How the data were processed

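Total RNA from mouse cells and brain was extracted with TRI reagent, copied into biotin-labelled cRNA with the TotalPrep kit and hybridised to Illumina mouse BeadChips, per the labels' protocols. GenomeStudio is named by the submitters' processing notes, with no version or role. The deposited intensity values are bead-averaged probe signals on a linear scale with no background subtraction, per the file headers and the values. A detection p-value is deposited for each probe and array, per the file headers. It was taken here to rank the signal among negative control beads, which the headers do not state. The authors' scaled intensity values equal these signals times 1 factor per array, so that every array has a mean of 229; they are linear, uncentred and not background-subtracted, with column medians of 38.8 to 61.0, and the ratio was constant within each array to a relative 9.3e-07 or less. No genome build is given in the sources used here, and no coordinates are printed.

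Each sample's group came from its title. The 18 arrays fall into 6 groups of 3, described as biological replicates in the series' design text. No 2 arrays of a group shared more than 1 identical signal value. Slide and scan date are not given in the sources used here.

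Of 45281 probes, 34885 have 1 gene symbol in the platform annotation used, 18 have several and 10378 are not listed there. Gene IDs of 34807 probes matched the RefSeq gene table (GRCm38.p6, used for names alone), and 0 symbols changed. Unnamed probes and those with several symbols were left out of gene tests. A gene whose probe has no name, or lies under detection, was not analysed here, and an undetected probe shows nothing about its gene.

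The background was corrected with a normexp model whose control mean and spread were inferred from the detection p-values, an offset of 16 was added, and arrays were quantile-normalized and taken to log2 with limma 3.58.1 in R 4.3.3. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and plots. Probes with detection p under 0.01 on at least 3 arrays numbered 23771, of which 19872 had 1 symbol. The probe with the highest mean stood for its gene, giving 12094 genes, of which 5069 had several detected probes. Among genes named or listed and passing, Mbp alone had other probes that passed in the opposite direction. Folds of dim genes are understated by the offset, and log2 values under other settings are fitted differences, not bounds, where a group was undetected.

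A linear model over all 18 arrays with 6 group means and no block was fitted with limma (lmFit and eBayes), so that the groups shared an estimate of spread. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, two-sided, in each of 7 comparisons. Brain was set against the mean of the 5 immune group means. The 26 gene lists, 7 marker lists, 7 comparisons with their tests and all alternatives but 2 were fixed before the data were examined; those 2, and the closing section's tests of explanations other than splits of the arrays, were chosen later. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 46 tests. Genes were named by a rule: the 8 largest changes in each direction among passing genes whose groups did not overlap, without clone-like names, and up to 3 passing members and 1 other of each list. List members given without a value were named because their count was small, after their values were seen.

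The replicate numbers, which the titles give, paired Th1 with Th2 arrays: deviations from the group means correlated at 0.592, 0.316 and 0.675 for the 3 pairs, and all 6 arrays correlated best with their own number. No other pair of groups had all 3 correlations over 0.1. Naive CD4 T cell and brain arrays also matched by number for all 6, but at correlations of only 0.031, 0.034 and 0.019. A match by number is therefore no sign of pairing by itself.

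The model was tested on simulated data for 12094 genes, with 200 changed genes per fold size. For Th1 against Th2, 95 of 200 genes changed by 2-fold passed, 196 changed by 3-fold and 200 changed by 8-fold, and 3 unchanged genes passed. A 2-fold change lies at the fold threshold itself, and 185 of those 200 genes met the adjusted p. The simulated noise was independent between genes and arrays, with a gene's spread the same in all groups and no pairing of Th1 with Th2. The count of unchanged genes that passed therefore need not hold for the real arrays. Alternatives covered the background correction, offset, scaling between arrays, the authors' scaled signal, detection filter, probe choice, arrays in the fit, replicate block, variance model, fold threshold and leaving out each array.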

Results

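Gene expression was measured in 5 kinds of mouse immune cell and in whole brain, with 3 biological replicates of each, on 18 Illumina BeadChip arrays. The immune samples were naive CD4 T cells (helper T cells that have not met antigen), Th1 and Th2 cells (the helper subsets known for interferon gamma and for interleukin 4, respectively), B cells (the antibody lineage) and dendritic cells (antigen-presenting cells). The immune samples were labelled as C57/BL6 and as male and female together, and the brain samples as male. Probes detected per array (detection p under 0.01) numbered 14614 to 15161 in naive CD4 T cells, 12564 to 14726 in Th1 cells, 13435 to 14177 in Th2 cells, 15170 to 15848 in B cells, 15204 to 16259 in dendritic cells and 20377 to 20497 in brain. Background signal was 34.4 to 39.0 on the T cell arrays and 34.6 to 37.7 on the brain arrays, but 49.2 to 54.9 on the B cell arrays and 46.6 to 48.0 on the dendritic cell arrays. This split follows the groups, so it cannot be told apart from them in comparisons of B or dendritic cells with T cells or brain. Arrays of a group correlated at r = 0.970 to 0.996 across genes, which are not independent replicates. Across groups, mean r was highest for Th1 with Th2 cells (0.963), and brain stood at 0.441 to 0.497 from each immune group. The number of arrays limits the precision of each value. In all, 12094 genes were tested.

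**Figure D1:**
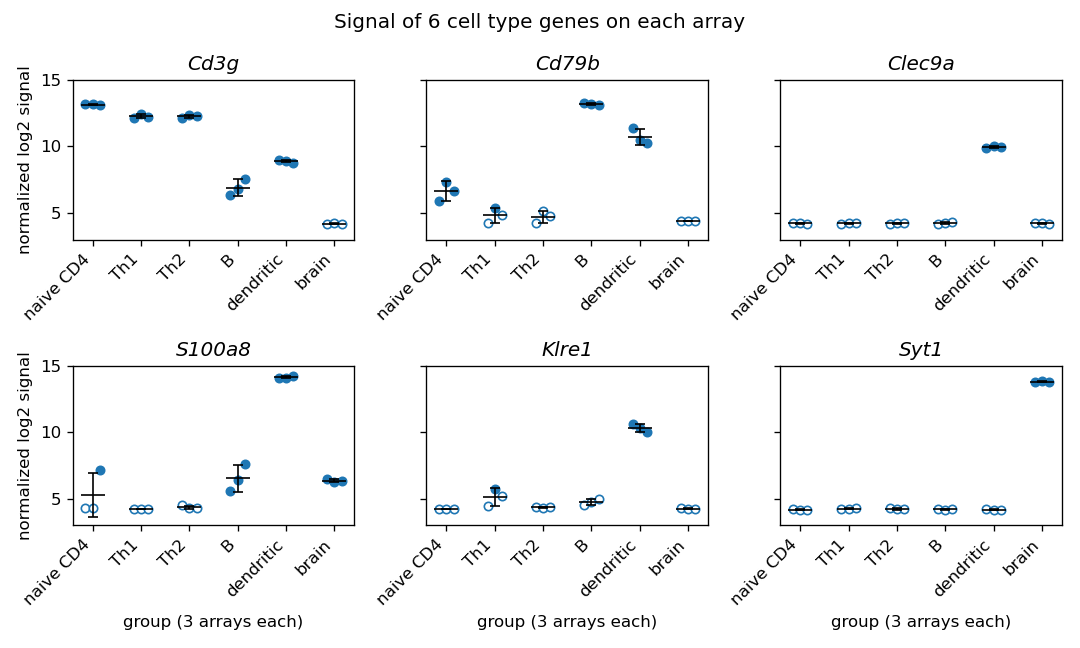
Normalized log2 signal (vertical axis) of 6 cell type genes on each array, by group (horizontal axis). Filled points are detected (detection p under 0.01), open points undetected and bars the mean ± SD of 3 arrays; the dendritic cell arrays, where Clec9a, S100a8 and Klre1 were highest, also carried Cd3g at 8.90 ± 0.10 and Cd79b at 10.72 ± 0.61.

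The first comparison asked how brain, a non-immune tissue, differed from the immune cells. Brain arrays carried high signal from genes of neurons and glia. Syt1, the calcium sensor of synaptic vesicles, reached log2 13.79 ± 0.05 (SD, n = 3) in brain against 4.21 ± 0.04 (SD, n = 15) in immune cells, at least 376-fold higher. Ttr, the thyroid hormone carrier made by choroid plexus, was at least 554-fold higher, Snurf at least 411-fold, the synaptic protein gene Cplx1 at least 321-fold and the myelin tight-junction gene Cldn11 at least 304-fold. These folds are lower bounds, because the probe was undetected on every array of the dimmer group; they set the brighter group against the lowest signal called detected there. Leukocyte genes went the other way. Cd52, a small surface glycoprotein of lymphocytes, differed by log2 -8.10 ± 0.08 (SE; limma adjusted p = 3.53e-21), Cytip, a regulator of leukocyte adhesion, was at least 248-fold lower, and Cd69, an early activation marker, at least 142-fold lower.

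By fixed lists, all 17 measured neuron genes and all 14 astrocyte genes were higher in brain, among them Rbfox3 (at least 124-fold), Slc1a3, the glial glutamate transporter (log2 8.37 ± 0.20), and the glycolytic enzyme gene Aldoc (log2 6.40 ± 0.12). Of 12 oligodendrocyte genes, 10 were higher, 1 was lower and 1 did not pass. The lower one was Mbp, myelin basic protein, and its probes disagreed. The probe chosen by the rule gave log2 -2.59, while 4 other Mbp probes were higher in brain, the brightest by 8.83 ± 0.11 (SE; limma adjusted p = 1.12e-19). Of 14 vessel genes, 10 were higher, including the endothelial claudin Cldn5 (at least 9.32-fold), 1 was lower (Pecam1, also a leukocyte adhesion molecule) and 3 did not pass. Microglial genes were higher for 11 of 13, led by Fcrls (log2 3.56 ± 0.18), but the list's call was lost at adjusted p = 0.199 with an estimated correlation. Among 22 homeobox and other developmental regulators, the measured ones of 44 listed, 16 were higher in brain, 2 were lower (Hoxa7 and Hoxb4) and 4 did not pass. The zinc finger gene Zic1 (at least 58.1-fold) and En2 (at least 13.0-fold) were among the higher. Both were detected on no immune array, so the brain arrays alone brought them through the detection filter. The same holds for Rbfox3, and counts with such genes lean towards brain. Of 22 pan-leukocyte genes 21 were lower, including the GTPase gene Rac2 (at least 81.9-fold), and Evl was higher. Cell cycle genes were lower for 21 of 24, for example the centromere histone Cenpa (log2 -5.01 ± 0.14) and the replication helicase subunit Mcm5 (log2 -4.46 ± 0.10). Of 21 factors of DNA methylation and CpG islands, 9 were lower, with Uhrf1, which recruits the maintenance methyltransferase, at log2 -4.46 ± 0.16 and the de novo methyltransferase Dnmt3b at log2 -3.63 ± 0.10. In the same list 2 were higher (Cxxc4, at least 5.63-fold, and Cxxc5) and 10 did not pass, and its call was lost at adjusted p = 0.1 with an estimated correlation. List tests gave adjusted p from 5.62e-10 for neuron genes to 0.00709 for microglial genes among the lists higher in brain, and 7.4e-09 for pan-leukocyte, 2.9e-07 for cell cycle and 0.0302 for DNA methylation and CpG island genes, which were lower. The erythroid marker Hba-a1, a haemoglobin chain, was at log2 13.89 ± 0.27 (SD, n = 3) in brain, beside these groups. The stress and dissociation genes had a median of log2 5.23 in brain, the lowest of all groups, against 6.89 in naive CD4 T cells to 11.57 in dendritic cells.

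In total 6327 genes passed in brain against the mean of the immune groups, 3113 higher and 3214 lower. Of the passing genes 49.2% were higher in brain, but 64.0% were with median scaling and 64.1% with the authors' scaled signal. Counting only genes that passed in the same direction against each of the 5 immune groups left 3813, of which 2289 were higher and 1524 lower in brain.

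B cells were compared with naive CD4 T cells. All 18 measured B cell identity genes were higher in B cells, and 15 of 17 T cell identity genes were lower. The B lineage kinase gene Blk was at least 129-fold higher, the Fc receptor-like gene Fcrla differed by log2 7.46 ± 0.37 and the desaturase gene Scd1 was at least 107-fold higher. Cd3g, a chain of the T cell receptor complex, differed by log2 -6.23 ± 0.20 (SE; limma adjusted p = 3.8e-13), the T lineage transcription factor gene Bcl11b by log2 -6.45 ± 0.30 and Thy1 by log2 -6.16 ± 0.22. Cd5 and Cd2 did not pass. Cd5 had a fitted log2 of -0.97 (limma adjusted p = 0.0035). Its probe was undetected on all B cell arrays and dim on the naive ones, at log2 5.35 ± 0.43 (SD) and detected on 2 of 3. That leaves at least 1.18-fold lower in B cells. The fitted value passed without naive replicate 2 (-1.22), without B cell replicate 1 (-1.05) and with median scaling (-1.30). All 13 genes of MHC class II antigen presentation were higher in B cells, such as H2-Aa (log2 7.06 ± 0.27) and H2-Eb1 (log2 6.59 ± 0.35, and 5.98 without naive replicate 1). Of 16 naive T cell genes, 11 were lower in B cells, led by Pdlim4 (log2 -6.43 ± 0.20), Igfbp4 (log2 -6.37 ± 0.24) and the interleukin 7 receptor Il7r (log2 -5.59 ± 0.23), and 5 did not pass. Of 7 plasma cell genes, 2 were higher, Mzb1 (log2 6.95 ± 0.47) and Irf4 (log2 4.56 ± 0.35), and 5 did not pass. List tests gave adjusted p from 6.28e-25 for B cell identity to 0.00114 for plasma cell genes. The B cell arrays also carried T cell markers at a median log2 of 6.20, against 11.69 in naive CD4 T cells. Their stress and dissociation genes had a median of log2 9.45, against 6.89, and their erythroid markers 6.05, against 4.52. Of 7 myeloid markers 4 were detected on all 3 B cell arrays, against 1 on the naive ones. The naive arrays in turn carried some B cell signal. Cd79b, Fcmr and H2-Eb1 were detected on all 3 of them, at mean log2 6.64, 6.98 and 7.44, though 4 of 6 measured B cell markers were detected on none. The total was 1720 genes, 883 higher and 837 lower in B cells, and 1121 without background correction.

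Dendritic cells were set against naive CD4 T cells. All 16 dendritic cell genes were higher, among them Clec9a, a receptor for dead cells (at least 26.8-fold), the transcription factor gene Batf3 (at least 22.1-fold) and the costimulatory receptor Cd40 (log2 5.55 ± 0.20; limma adjusted p = 6.98e-13). All 13 MHC class II genes were higher, with H2-Aa at log2 7.11 ± 0.27. S100a8 and S100a9, the subunits of calprotectin, differed by log2 8.91 ± 0.57 and 8.29 ± 0.33, and the cytokine gene Il1b by 8.47 ± 0.32. All 3 were detected on 1 of 3 naive arrays, so these are fitted values. Without naive replicate 3 S100a8 was undetected in naive cells and at least 493-fold higher in dendritic cells. Lactoferrin, Ltf, was at least 220-fold higher and Lcn2 at least 145-fold higher. S100a8, S100a9, Ltf and Lcn2 are members of the fixed granulocyte list, and whether dendritic cells themselves expressed them was not tested. Macrophage and monocyte genes were higher for 14 of 16, such as lysozyme Lyz2 (log2 7.75 ± 0.39, and at least 189-fold without naive replicate 3, the 1 naive array that detected it) and the galectin Lgals3 (log2 6.91 ± 0.27). Innate sensing genes were higher for 12 of 16, such as the lectin receptor Clec4d (at least 18.4-fold) and Tlr13 (at least 15.4-fold). Cell cycle genes were higher for 15 of 24, led by Birc5 (log2 3.40 ± 0.25), Cdk1 (log2 3.22 ± 0.23) and Bub1b (log2 3.11 ± 0.26), and 9 did not pass. All 17 T cell identity genes were lower, including Lef1 (at least 28.2-fold) and Bcl11b (log2 -4.72 ± 0.30). List tests gave adjusted p from 1.06e-14 for dendritic cell to 1.25e-08 for innate sensing genes. Beside these groups, the dendritic cell arrays carried markers of other cells, named after their values were seen. All 5 measured NK and CD8 T cell markers were detected on all 3 arrays, with Klre1 at log2 10.31 ± 0.30, though Cd8b1 among them was detected in every group. Of 6 T cell and of 6 B cell markers, 5 each were detected on all 3 arrays, with medians of log2 8.14 for both. Hba-a1 stood at log2 12.25 ± 1.23, and the stress and dissociation genes had a median of log2 11.57, against 6.89 in naive CD4 T cells. The total was 2785 genes, 1596 higher and 1189 lower, and 1812 without background correction. Of the passing genes 57.3% were higher in dendritic cells, but 72.6% were with median scaling.

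Between dendritic cells and B cells, both of which present antigen, the MHC class II genes did not move as a group. Of 13, only H2-Ob, part of an inhibitor of peptide loading, passed, at log2 -1.73 ± 0.17 (SE; limma adjusted p = 4.29e-07), and the list test gave adjusted p = 0.573. The list's median was 0.04, its mean was -0.16, and the sign of the median turned with the authors' scaled signal and, relative to all genes, with median scaling. Of 16 dendritic cell genes, 13 were higher in dendritic cells, including Clec9a (at least 28.8-fold) and the actin bundler Fscn1 (log2 4.44 ± 0.21), and 3 did not pass. Cd40 did not pass, at log2 -0.91 with adjusted p = 0.00178, but did with the authors' scaled signal (-1.04) and with all probes kept (-1.01). All 10 granulocyte genes were higher, for example Ltf (log2 8.08 ± 0.29), Retnlg (at least 83.3-fold) and Ngp (at least 94.3-fold), and the markers of NK, T and red cells given above stand beside this list too, with stress and dissociation genes at a median of log2 11.57, against 9.45 in B cells. Innate sensing genes were higher for 11 of 16, with Clec7a at least 10.4-fold, and Tlr1 was lower. All 18 B cell identity genes were lower in dendritic cells, led by the low-affinity IgE receptor Fcer2a (log2 -4.72 ± 0.23), Vpreb3 (log2 -3.85 ± 0.22) and the follicle-homing receptor Cxcr5 (log2 -3.46 ± 0.25). List tests gave adjusted p = 5.63e-15 for B cell identity, 3.87e-14 for granulocyte, 2.8e-11 for dendritic cell and 2.53e-07 for innate sensing genes. With estimated correlations (0.397 for B cell identity, 0.410 for granulocyte genes) the same tests gave 0.0143, 0.00563, 0.000105 and 0.000495. The total was 1783 genes, 1235 higher and 548 lower in dendritic cells, and 1169 without background correction. Of the passing genes 69.3% were higher, but 82.6% were with median scaling and 64.6% with the authors' scaled signal.

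Th1 cells were compared with the naive cells that helper subsets arise from. Il3, a growth factor of blood cells, was at least 568-fold higher, the chemokine Ccl3 at least 542-fold, the T cell growth factor Il2 at least 360-fold, Il10 at least 284-fold and Csf2 at least 158-fold, and the metallothionein gene Mt1 differed by log2 8.36 ± 0.24. Ifng, the signature cytokine of Th1 cells, differed by log2 9.73 ± 0.50 (SE; limma adjusted p = 7.11e-11), from 4.77 ± 0.63 to 14.50 ± 0.05 (SD, n = 3 each). Klf2, which keeps naive T cells circulating, fell by 7.08 ± 0.31 on the log2 scale, and Pdlim4 was at least 61.6-fold lower. Of 17 Th1 genes 15 rose, while Stat4 did not pass at log2 -0.74. Activation genes rose for 15 of 18, including Bhlhe40 (at least 68.4-fold), Irf4 (log2 5.85 ± 0.35) and the inhibitory receptor Lag3 (at least 25.9-fold). Cell cycle genes rose for 19 of 24, led by Cdk1 (log2 4.28 ± 0.23) and Cdc20 (log2 4.18 ± 0.17). Glycolysis genes rose for 9 of 14, with Tpi1 at log2 3.30 ± 0.18 and Pgam1 at 2.53 ± 0.13, while Pfkm fell. Ldha, at log2 0.80, did not pass, but did with median scaling (1.57), cyclic loess (1.11) and the authors' scaled signal (1.12). Naive T cell genes fell for 11 of 16, and 7 of 12 cytotoxic effector genes rose, with Nkg7 at log2 6.19 ± 0.31. Among 21 DNA methylation and CpG island factors, 5 rose and 6 fell. Uhrf1 rose by log2 3.27 ± 0.21, whereas the methylcytosine oxidase Tet1 was at least 3.81-fold lower and the mismatch glycosylase Mbd4 at least 2.58-fold lower. That list did not shift as a whole (adjusted p = 0.747), and the sign of its median turned with median scaling. Beside these groups, the stress and dissociation genes had a median of log2 7.92 in Th1 cells, against 6.89 in naive cells. The other list tests gave adjusted p from 2.48e-12 for activation to 0.00374 for cytotoxic effector genes. The total was 3438 genes, 1577 higher and 1861 lower. Of the passing genes 45.9% were higher, but 59.1% were with median scaling and 35.2% with the authors' scaled signal.

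Th2 cells were compared with naive cells in the same way. Il4, the signature cytokine of Th2 cells, was at least 575-fold higher, at log2 14.38 ± 0.01 against 4.65 ± 0.32 (SD, n = 3 each). Il24 was at least 465-fold higher, Il3 at least 563-fold, Il10 at least 279-fold and the chemokine Ccl1 at least 208-fold. Ifng was higher too, by log2 8.87 ± 0.50 (SE; limma adjusted p = 2.36e-10). Klf2 was at least 120-fold lower, the actin regulator gene Ripor2 at least 56.8-fold lower, and Txnip, an inhibitor of glucose uptake, fell by 5.36 ± 0.38 on the log2 scale. All 13 Th2 genes rose. Activation genes rose for 16 of 18, such as the receptor Havcr2 (at least 33.1-fold), cell cycle genes for 16 of 24, such as Cdk1 (log2 4.07 ± 0.23) and Tyms (log2 3.26 ± 0.17), and glycolysis genes for 10 of 14, such as Tpi1 (log2 3.05 ± 0.18), with Pfkm lower. Naive T cell genes fell for 13 of 16. Of 12 cytotoxic effector genes 5 rose and 2 fell, with granzyme Gzmd at least 26.0-fold higher, and the list test gave adjusted p = 0.0643. Of the 21 DNA methylation and CpG island factors 5 rose, among them Uhrf1 (log2 2.93 ± 0.21) and Tdg (log2 1.79 ± 0.12), and 5 fell, among them Tet1 (at least 3.83-fold lower). The list test gave adjusted p = 0.895, and the sign of the list's median turned with median scaling and with cyclic loess. Beside these groups, the stress and dissociation genes had a median of log2 8.0, against 6.89 in naive cells. The other list tests gave adjusted p from 1.25e-12 for Th2 to 3.4e-05 for glycolysis genes. The total was 3260 genes, 1522 higher and 1738 lower. Of the passing genes 46.7% were higher, but 61.6% were with median scaling and 37.95% with the authors' scaled signal.

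Both subsets were set against the same 3 naive arrays, which by itself makes their changes alike. Higher in both were 1211 genes, where independent lists of these sizes would share 198, and lower in both were 1470, against 267. In 20 simulations with shared controls and no effect the overlap was 0 in each direction, which is chance without effects and does not measure what shared controls add to these overlaps. The naive arrays were not divided between the subsets, since with 3 arrays 1 side would keep only 1, and part of the excess over independent lists may come from them. The covariance of the fold changes across genes was 1.36, against 0.0199 simulated, and shared controls add the same covariance with or without effects. The correlation was 0.919, against 0.50 simulated, a difference that does not estimate a shared effect.

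The direct comparison of Th1 with Th2 cells tested which changes differed between the subsets. Higher in Th1 cells were the interleukin 18 receptor chains Il18r1 (at least 31.8-fold) and Il18rap (log2 3.37 ± 0.19), and the chemokine receptors Cxcr1 (at least 84.9-fold) and Cxcr2 (at least 6.79-fold). Higher in Th2 cells were Gata3, the master transcription factor of that subset (log2 -4.21 ± 0.18 for Th1 minus Th2; limma adjusted p = 1.79e-10), the chemokine receptor Ccr8 (log2 -4.84 ± 0.24), the eosinophil growth factor Il5 (log2 -3.76 ± 0.29) and the ephrin Efna5 (at least 19.7-fold). Ifng was at 14.50 ± 0.05 in Th1 and 13.63 ± 0.15 in Th2 cells (SD, n = 3 each), a difference of log2 0.86 ± 0.50 that did not pass (adjusted p = 0.317). This SE and p rest on a spread shared by all 6 groups, which is wider here than the SDs of the Th1 and Th2 arrays. They do not measure the spread of those arrays, whose SDs are far smaller than the difference. Il10 did not pass either, at 0.03 ± 0.32. Speer3 (log2 4.02 ± 0.37), Speer1 and Speer6-ps1 (at least 4.98-fold) were higher in Th1 cells, but these are closely similar copies, so which member was measured is uncertain.

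Of 13 Th2 genes 12 were higher in Th2 cells, and of 17 Th1 genes 6 were higher in Th1 cells, 10 did not pass and Havcr2 was higher in Th2 cells (log2 -1.64 ± 0.13). These list tests gave adjusted p = 3.81e-24 and 9.83e-07. Interferon-stimulated genes were higher in Th2 cells for 14 of 17, led by the antiviral genes Rsad2 (log2 -3.80 ± 0.45, but -3.18 without Th1 replicate 1 and -4.45 without Th1 replicate 2), Ifit3 (log2 -2.94 ± 0.28) and Oasl2 (log2 -2.93 ± 0.30), while the guanylate-binding proteins Gbp2 and Gbp3 were higher in Th1 cells. That list's adjusted p was 1.96e-14, and 0.0193 with an estimated correlation. The probe annotated to the interferon alpha gene Ifna5 was also higher in Th2 cells (log2 -3.88 ± 0.31), but whether it is specific to that member of the family was not tested. Cytotoxic genes divided, with the NK receptor genes Klrd1 (log2 2.50 ± 0.22) and Klrk1 (at least 2.70-fold) among 5 higher in Th1 cells and Gzmd (log2 -3.00 ± 0.20) and Gzme higher in Th2 cells, and the list test gave adjusted p = 0.139. Klrk1 did not pass with the authors' scaled signal (0.92). No gene of 15 in sterol synthesis passed, yet the list as a whole shifted towards Th1 cells (adjusted p = 0.000766). Lss moved the other way, at log2 -0.72, and passed without Th1 replicate 1 (-1.11). Of 24 cell cycle genes 2 passed, Bub1b (log2 1.01 ± 0.26) and Tpx2 (log2 1.01 ± 0.23). Both calls ended without Th1 replicate 1 (0.84 for Bub1b, 0.76 for Tpx2) and without Th2 replicate 3 (0.84 and 0.80). The Bub1b call also ended without Th1 replicate 2 (0.98), and the Tpx2 call without Th2 replicate 2 (0.89). Both ended without background correction (0.94 and 0.52) and with offset 50 (0.95 and 0.56), and in a fit of the Th1 and Th2 arrays alone with no block (adjusted p = 0.0786 and 0.187). The Tpx2 call ended too with median scaling (0.46), cyclic loess (0.65) and the authors' scaled signal (0.24). The cell cycle list test gave adjusted p = 0.0747. Of 8 regulatory T cell genes, Itgae (log2 -1.40 ± 0.29) and Izumo1r (at least 1.67-fold) were higher in Th2 cells and 6 did not pass, Foxp3 among them at log2 -0.53. Both calls ended without background correction (-0.75 for Itgae, -0.81 for Izumo1r), with offset 50 (-0.80 and -0.86), with cyclic loess (-0.88 and -0.84) and with the authors' scaled signal (-0.66 and -0.70), and that of Itgae with median scaling (-0.97) and in the fit of the Th1 and Th2 arrays alone with no block (adjusted p = 0.0922). The list test gave adjusted p = 0.0962, and the sign of the list's median turned with median scaling, with cyclic loess and, relative to all genes, with the authors' scaled signal. The total was 544 genes, 264 higher in Th1 and 280 higher in Th2 cells, with 290 without background correction, 314 with offset 50 and 345 with the authors' scaled signal.

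**Figure D2:**
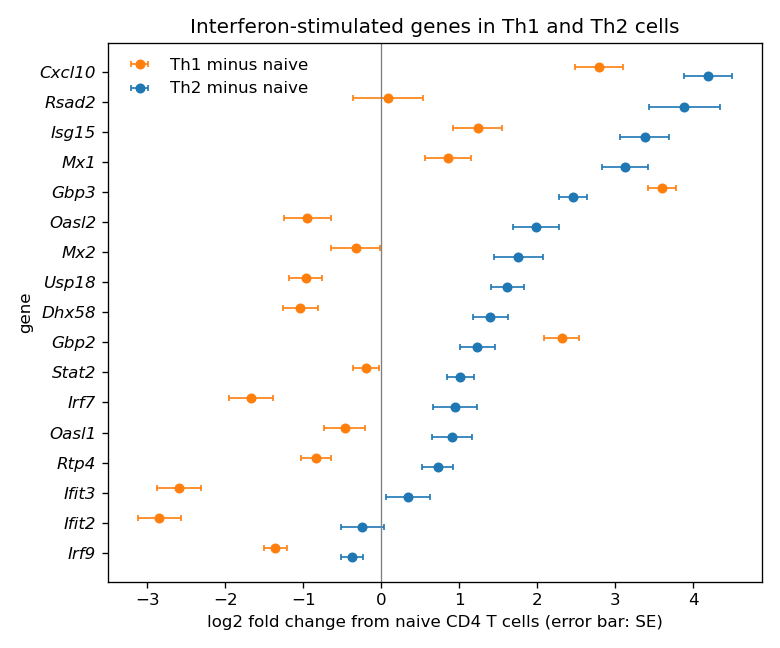
Log2 fold change from naive CD4 T cells (horizontal axis, error bar SE of the limma fit, 3 arrays per group) of 17 interferon-stimulated genes (vertical axis) in Th1 cells (orange) and Th2 cells (blue). Between the subsets 14 genes were higher in Th2 cells, and Gbp2 and Gbp3 were higher in Th1 cells.

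Across the 46 list tests, counts adjusted over the list alone were the same as those adjusted over all genes in each list. The lists called with the preset correlation kept their calls with an estimated correlation, except microglia and the DNA methylation and CpG island factors in brain. Where the genes of a list vary together, however, the preset correlation gave far smaller p-values. For B cell identity in B against naive cells, the list test's adjusted p was 6.28e-25 preset and 0.00359 with the estimated correlation of 0.397.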

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

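Of the tests in this part, those of the T and B cell transcripts and of the interferon-stimulated genes were chosen after the result was seen, while the splits of the arrays were not.

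The change from naive cells differed between Th1 and Th2 cells, by the test of the difference itself, for 544 genes. The 18 given here are 11 of the 50 genes named for either subset against naive, and 7 in which the subsets moved in opposite directions, each past the threshold, which were chosen after their values were seen. The values are fitted log2 differences, Th1 minus Th2, and are no bounds where a subset's probe was undetected. Cxcr1 (fitted 6.85) and Il18r1 (fitted 6.08) were undetected on all 3 Th2 arrays, which leaves at least 84.9-fold and at least 31.8-fold. The difference was 4.02 for Tubb2b, 2.08 for Scly, -2.44 for Dhx58, -3.03 for Cmpk2 and -4.21 for Gata3. Genes that rose in both, but more in Th2 cells, were Il4 (-2.67), Gzmd (-3.00), Il24 (-2.08), Havcr2 (-1.64) and Ccl1 (-1.31). Those that rose more in Th1 cells were Nkg7 (1.37) and Bub1b (1.01), but the difference in Bub1b did not pass without Th1 replicate 1 (0.84), Th1 replicate 2 (0.98) or Th2 replicate 3 (0.84). Pdlim4 (fitted -1.57) and Galnt10 (fitted -2.52) were undetected on all 3 Th1 arrays, which leaves at least 1.60-fold and at least 3.97-fold lower in Th1 cells. Stat4 (1.55) passed against naive in Th2 cells alone, and Ly6c1 (1.41) in neither subset. Ly6c1 did pass as higher in Th1 than naive cells with median scaling (1.64), cyclic loess (1.35) and the authors' scaled signal (1.19). It also did without Th1 replicate 1 (1.03).

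Outside the named genes, 3899 probes with no single gene name were detected on at least 3 arrays, and 1754 of them passed in brain against immune cells.

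T and B cell transcripts appeared on the dendritic cell arrays, with Cd3g at log2 8.90 ± 0.10 and Cd79b at 10.72 ± 0.61 (SD, n = 3); T cell identity genes had a median of 7.43% of their naive signal and B cell identity genes 14.2% of their B cell signal. A raised array background was argued against: these arrays' background rose by 9.52 to 10.95 signal units over the naive arrays, while the smallest median of either list on any of them was 99.4 units over the array's own background, and the smallest lower quartile 32.7. Other cells in the preparations, for which no sort or gate is given in the sources used here, remain open: 94.1% of T and 94.4% of B cell genes lay within 4-fold of the median share, but 65.0% and 94.0% of 2000 random lists of genes lower in dendritic cells did as well, so this test decides nothing. All B cell genes (100%, 18 of 18) were higher on array 1 than on array 3, which 0 of 2000 random lists matched and which a differing share of B cells may explain. Those random lists were matched on level alone, while B cell identity genes vary together (estimated correlation 0.397), so the count cannot tell causes apart. T cell genes did not move so (7 of 17), and expression by dendritic cells themselves was not tested.

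Interferon-stimulated genes were higher in Th2 than in Th1 cells. A single replicate pair was argued against, since the smallest of the 3 pair medians was 1.15 log2. A share of dendritic or myeloid cells large enough to raise their own genes in the Th2 samples was argued against. Of 32 dendritic cell and macrophage genes, 2 passed as higher in Th2 cells and 4 as higher in Th1 cells. Only 10 of the 32 were detected on all 3 Th2 arrays, so this count cannot exclude a smaller share, which remains open. The subset itself, and any condition that differed with it, remain open and untested.

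Relabelled splits of the arrays gave fewer genes. In the comparison of brain, 1 of 100 drawn splits of 816 gave as many genes, the real one. It gave 5718 in a 2-group fit, against 0 as the highest other. Every other split leaves brain arrays among the immune arrays, which widens the spread within a side and keeps its count low. These splits therefore cannot exclude chance. With 3 against 3 arrays, 10 splits are too few for a share under 0.05, and 1 split, the real one, had the real count in each. The real count and the highest other were 1720 and 2 for B against naive cells, 2785 and 0 for dendritic against naive, 1783 and 22 for dendritic against B, 3438 and 1 for Th1 against naive, 3260 and 0 for Th2 against naive, and 544 and 85 for Th1 against Th2. Of the 4 splits of the last that part all 3 pairs, the real one included, the highest other gave 0, while the other splits hold 1 pair whole on each side.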

How the results depend on the processing

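Counts that moved by over 1.5 times were these. Without background correction, 1121 genes passed for B against naive, 1812 for dendritic against naive, 1169 for dendritic against B and 290 for Th1 against Th2 cells. The last was 314 with offset 50 and 345 with the authors' scaled signal. With no fold threshold the counts were 10464 for brain, 4235 for B against naive, 6166 for dendritic against naive, 4622 for dendritic against B, 6504 for Th1 and 6338 for Th2 against naive, and 1670 for Th1 against Th2, which follows from dropping a criterion. Against each of the 5 immune groups, 3813 genes passed in brain, a stricter criterion. For the other moves the cause was not tested. Leaving out each array in turn gave 6308 to 6337 for brain, 1694 to 1781 for B against naive, 2682 to 2894 for dendritic against naive, 1743 to 1873 for dendritic against B, 3386 to 3500 for Th1 and 3181 to 3322 for Th2 against naive, and 539 to 587 for Th1 against Th2. With the replicate block, 552 genes passed for Th1 against Th2. In a fit of those arrays alone, 411 passed with no block and 539 with it, the latter an alternative chosen after seeing the data, as was leaving the dendritic cells out of the immune mean (6397 for brain). The block changed no call of a named gene or list. The median of all genes moved by over 0.1 log2 with median scaling, to 0.31 in brain, -0.31 for B against naive, 0.35 for dendritic against B, 0.36 for Th1 and 0.53 for Th2 against naive, and -0.16 for Th1 against Th2. It moved so in brain with cyclic loess (0.21) and the authors' scaled signal (0.20), for B against naive with both (-0.14 and -0.17), for dendritic against B with cyclic loess (0.08) and for Th1 against Th2 with the authors' scaled signal (-0.13), so small changes are relative to the scaling. No call of a named gene reversed. Over settings other than leaving out an array, whether a named gene passed or not stayed the same 2588 times. Calls were lost 20 times and gained 40 times. Over left-out arrays these numbers were 1940, 6 and 22. The slide block was not run, since no slide is given in the sources used here. Signal over background limits dim genes, whose folds are bounds or understated.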

Other observations

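The test of sex in this part was chosen after its result was seen, as were the genes named.

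Klf2 was at log2 12.31 ± 0.18 in naive CD4 T cells, 12.46 ± 0.44 in B cells and 11.84 ± 0.68 in dendritic cells, but at 5.23 ± 0.42 in Th1 cells, 4.82 ± 0.32 in Th2 cells and 6.26 ± 0.36 in brain (SD, n = 3 each). Interferon-stimulated genes divided by subset against naive cells: in Th2 cells 11 of 17 were higher and 0 lower, while in Th1 cells 4 were higher and 5 lower. Their median log2 fold change was 1.40 in Th2 and -0.47 in Th1 cells, and kept its sign under the scalings tried. All 17 were lower in brain than in the immune mean, 17 with cyclic loess, 16 with median scaling or the authors' scaled signal, and 15 without background correction or with offset 50. Cd8b1, a CD8 T cell gene, was detected in every group, at log2 10.25 ± 0.46 in naive CD4 T cells and 7.90 ± 0.28 in brain. In brain all 6 measured T cell markers were undetected on every array, so the signal of this probe cannot be read as a sign of CD8 T cells.

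Xist, the RNA that silences an X chromosome in females, was undetected on the 3 brain arrays (log2 4.22) and between 9.08 and 9.86 in the immune groups. The sex of the animals, which the labels give as male for brain and mixed for immune cells, may account for this. The median log2 fold change of 3 Y-linked genes was 0.53. Eif2s3y was at 0.70 (limma adjusted p = 0.000188), Kdm5d at 0.53 (limma adjusted p = 0.0147) and Uty at -0.17. None reached the log2 threshold of 1, which male against mixed animals need not reach. Uty lay near the lowest signals called detected, at log2 4.89 in brain and 4.77 to 5.33 in the immune groups. The Y-linked genes therefore do not settle it, and sex remains confounded with tissue.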
